A study of Danio rerio with 2 samples.

How the data were processed

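Guts were dissected from zebrafish larvae given as 5 dpf in the labels, 10 per tube, and 5 tubes were pooled into 1 library without injury and 1 library taken 24 h after transection of the intestine. Per the labels' protocols the tissue was digested with enzymes, live cells were taken from a density gradient, and libraries were made with a droplet 3' kit of V2 chemistry. Per the submitters' processing notes the reads were processed with Cell Ranger on the danRer11 genome, and per the file headers the version was 9.0.1. The deposited matrices hold raw counts (UMI counts per gene and barcode) for 27771 genes, and they list 2002472 uninjured and 1639285 transected barcodes, with 164944360 and 119017362 UMIs, so cells were called here. The authors' own cell calls and cluster names were not used here.

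Barcodes with at least 500 UMIs numbered 9828 and 10319. Their profiles were compared with the ambient RNA of their library (barcodes of 1 to 100 UMIs) in a multinomial Monte Carlo test with 10000 draws. Barcodes above the knee, or above a lower fixed UMI limit, were kept without a test, which holds for most uninjured cells kept. Barcodes kept in this way or passing the test (Benjamini-Hochberg adjusted value at most 0.001) numbered 6907 and 6737. Cells needed at least 250 genes and at most 25% mitochondrial UMIs. Doublets were scored per library with Scrublet as built into scanpy; its own threshold marked 2 and 0 cells, so, as set in advance for that case, the highest 4% of scores were dropped (270 and 262 cells). This left 6149 and 6035 cells, with 81.5% and 76.2% of UMIs in cells, a median of 8638 and 2796 UMIs and of 2113 and 976 genes per cell.

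Both libraries were clustered together with no batch integration: counts per 10000, log scale, 2000 variable genes, 30 principal components, 20 neighbours, Leiden resolution 1. Clusters were named from 26 fixed marker lists; a name needs at least 3 detected markers and leading genes that go with it, and other clusters are given by number. A named class is a likeness in markers (enteroendocrine-like and so on). Clusters whose cells have a median UMI count, in both libraries, under the library median divided by 3 were kept apart as low-UMI barcodes, a choice made after the data were seen. Genes that lead a cluster are not given singly as results for that cluster's class, but the list medians include them.

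Shares of cells have exact Clopper-Pearson intervals of 95%. For classes with at least 50 cells in each library, counts were summed per class and library and given per 1000000 of the class's UMIs without mitochondrial genes (CPM), with exact Poisson intervals for sums and exact conditional intervals for ratios (transected over uninjured), which cover counting error only. A count of 0 was set to a floor of 3 counts over the class for a ratio. With 1 library per group no test, p-value or standard error was computed. Of 27 fixed gene lists, members with at least 20 counts in the higher library were used, and the median log2 ratio was set beside 10000 random lists of the same size matched on expression, as a description of these 2 libraries. A list is described as higher or lower when its percentile is at least 97.5 or at most 2.5, with all members and with those at or above the ambient level; of 332 lists measured over 13 classes, 24 were higher and 35 lower.

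Before the data were examined, the genes to name were fixed by size: at least 100 UMIs, in at least 10% of cells and at or above the ambient level in the higher library; of these the 12 highest and 12 lowest ratios in the 3 named intestinal classes with most cells (absorptive enterocyte, BEST4/OTOP2 and lysosome-rich enterocyte), the 4 highest and 4 lowest in other classes, the IL-10 family genes, and up to 4 members of each list. The text gives part of these, chosen for known function after the values were seen, and 1 gene the rule picks is not reported here. Cycling cells were those with at least 2 UMIs of G2/M genes after thinning every cell to 1000 UMIs. The BEST4/OTOP2 and mesenchyme classes were split into their clusters, and the share of a gene's UMIs held by 5 cells was added, after sums were seen to rest on few cells or on the mix of clusters.

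Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used, with fixed seeds. Ratios and lists were tested on simulated data with 200 genes of known fold in 2 classes. In absorptive enterocyte-like cells (23713 genes) the 95% intervals held the true ratio for 97 and 95 of 100 genes (2-fold and 4-fold, transected against uninjured). In enteroendocrine-like cells (17205 genes) they held it for 94 and 94 of 100. Of 200 lists of unchanged genes 8 passed a percentile limit in each class. The simulated sums were drawn gene by gene as Poisson counts, without cells. They leave out uneven spread over cells and correlation between genes, so they check the calculation and not the spread of real sums.

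Alternatives covered the UMI minimum (1000 and 2000), the mitochondrial maximum (10%), doublets kept, median-of-ratios scaling, equal weight of cells, subtraction of ambient RNA, sums thinned to equal median depth, Leiden resolution 0.5 and 2, the count minimum of list members, pseudocounts, and the rule and depth for cycling cells. The Leiden settings were not run for single genes, nor for shares and lists of numbered clusters. Added after the data were seen were low-UMI clusters left out or counted as enterocytes, members at or above the ambient level, the deepest 5% of cells left out, and the 5% of cells with most UMIs of each gene left out. For the lists weighed at the end, every cell was also thinned to 1000 UMIs.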

Results

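Cells from dissected guts of zebrafish larvae, given as 5 dpf in the labels, were compared between an uninjured library (6149 cells) and a library taken 24 h after transection of the intestine (6035 cells), each from 50 pooled guts. In the transected library an epithelial cluster, cluster 8, held more transcripts of the neutrophil chemokine genes cxcl8a and cxcl18b, of the epithelial cytokine gene il17c and of genes for DNA synthesis. Lysosome-rich enterocyte-like cells held fewer transcripts of the endocytic receptor genes lrp2b, cubn and amn, which are also among the markers that named this class. Absorptive enterocyte-like cells held fewer interferon-response transcripts such as ifit15. Enteroendocrine-like cells held 15 of 24 uninjured and 17 of 19 transected UMIs of the IL-22 gene il22. The design has 1 library per group and no replicates, so every interval given is a 95% interval that covers counting error only, and no test between the groups was made. The age at transection was not known here, so a difference in age between the libraries is not excluded for any ratio.

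Absorptive enterocyte-like and BEST4/OTOP2-like cells held larger shares of the transected library, and cluster 27 a smaller one. Shares sum to the whole library, so fewer mesenchyme-like cells (11.5% and 1.74%) mean larger shares of other classes. A larger share therefore does not show that the cells of a class grew in number. Absorptive enterocyte-like cells (clusters 1, 2, 4 and 5), which take up fat, peptides and sugar, made up 25.5% (24.4 to 26.6) of uninjured and 32.1% (31.0 to 33.3) of transected cells, a ratio of 1.26 (1.18 to 1.35). The ratio was 1.57 at Leiden resolution 2 and 0.839 at resolution 0.5, where a cluster of 20 uninjured and 652 transected cells has no name. That cluster matches cluster 4 in cell numbers and median UMIs, so the value of 0.839 goes with a lost name. BEST4/OTOP2-like cells, known for ion and acid transport, made up 2.13% (1.78 to 2.52) and 4.34% (3.84 to 4.89), a ratio of 2.04 (1.65 to 2.53). Enteroendocrine-like cells held 1.69% and 1.54% and lysosome-rich enterocyte-like cells 2.23% and 1.86%, with ratios of 0.911 (0.681 to 1.22) and 0.833 (0.643 to 1.08). Cluster 26, led by stm, sparc, krt91 and krt94, held 17 uninjured and 103 transected cells, a ratio of 6.17 (3.67 to 11). Cluster 27, led by the junction genes cldnh and cldnb and by cnfn, held 97 and 9 cells, a ratio of 0.0945 (0.042 to 0.187).

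Mesenchyme-like cells, leukocytes and endothelium-like cells were scarce in the transected library. Mesenchyme-like cells, which make collagens and are not shown to come from the gut wall alone, made up 11.5% (10.7 to 12.4) of uninjured and 1.74% (1.43 to 2.1) of transected cells, a ratio of 0.151 (0.122 to 0.185). Of the 709 uninjured ones 247 lie in cluster 13, which is led by and2. Leukocytes numbered 99 and 6, endothelium-like cells 165 and 4, and cluster 17, led by the smooth muscle genes acta2, myh11a and tagln, 206 and 22. Clusters led by genes of tissue outside the gut were scarce too: cluster 9, led by the cartilage genes matn1, col2a1a and acana, held 305 and 8 cells, cluster 34, led by the heart genes myl7 and nppa, 57 and 0 cells, and hepatocyte-like cells 52 and 1, while exocrine pancreas-like cells numbered 72 and 17, a ratio of 0.241 (0.133 to 0.412). Stratified epithelium-like cells, led by the skin keratin gene krt5, numbered 72 and 0. At Leiden resolution 2 the ratio for that name was 1.15, because a cluster led by stm, sparc and krt91 (17 and 103 cells) also took it. The krt5-led cluster itself held 74 and 0 cells there. The dissection, the dissociation, the density gradient and the filter on UMIs can all set such shares.

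Barcodes with few UMIs took up much of the transected library. Clusters 0, 3, 6 and 25, whose cells hold few UMIs, made up 14.6% of uninjured and 40.5% of transected cells, and clusters 0, 3 and 6 among them carry enterocyte markers such as enpp7.1 and slc15a1b, genes for digestion of sphingolipids and uptake of peptides. The low-UMI class was set apart after the data were seen. Without it absorptive enterocyte-like cells made up 29.9% and 54.0%, but mesenchyme-like cells made up 13.5% and 2.93%, which raises the other shares. The median cell held 8638 UMIs in the uninjured and 2796 in the transected library.

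**Figure D1:**
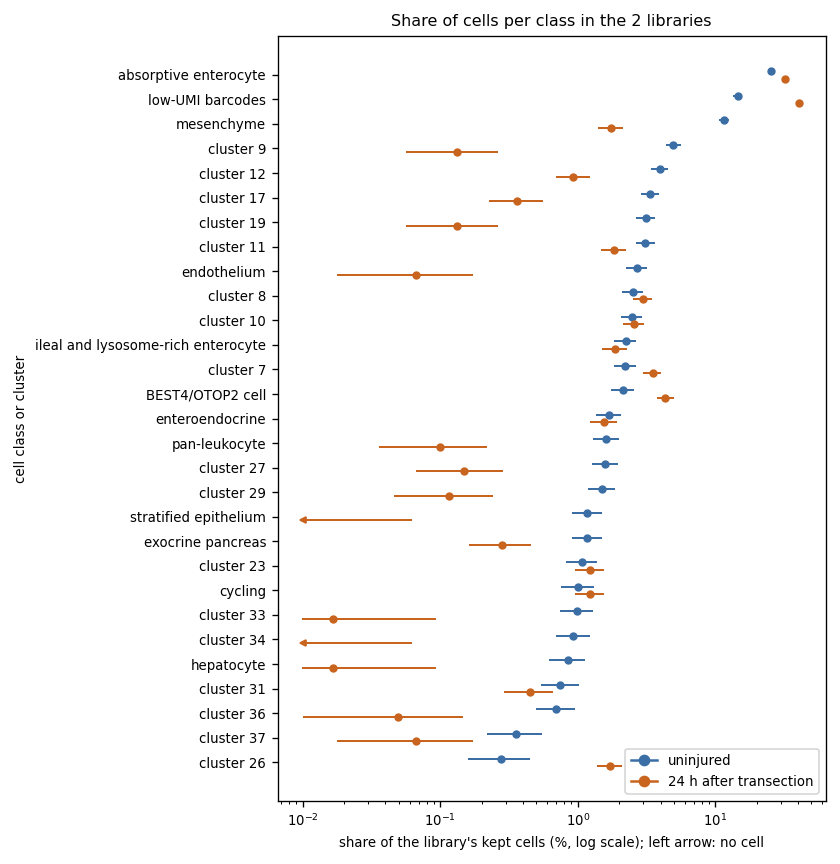
Share of kept cells per class or numbered cluster in the uninjured and the transected library, with exact 95% intervals that cover counting error only. Mesenchyme, endothelium and cluster 27 hold smaller shares in the transected library.

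Absorptive enterocyte-like cells of the transected library held fewer transcripts of some antiviral genes. The 16 measured interferon-response genes had a median log2 ratio of -0.40, with 6 at least 1.5-fold lower and 1 at least 1.5-fold higher, at percentile 0.05 of matched random lists. Among them ifit15, an interferon-induced gene, stood at 21.3 and 8.50 CPM (2.51-fold lower), and stat1b, which carries the interferon signal to the nucleus, at 4.77 and 0.578 CPM (8.24-fold lower). The antiviral gene rsad2 stood at 9.93 and 0.360 CPM, but 5 cells held 58.1% of its uninjured UMIs. The RNA sensor gene dhx58 was 2.04-fold lower. Lists of genes that other cells make, with members mostly under the ambient level, stood at -2.52 for matrix genes and -2.34 for gut hormone genes. Ambient RNA was put at 3.06% of the uninjured and 0.710% of the transected UMIs of the class. With ambient counts subtracted the interferon median was -0.39. These cells come from different clusters in the 2 libraries, since clusters 2 and 5 hold 1528 uninjured and 11 transected cells and clusters 1 and 4 hold 42 and 1928.

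A few genes of protein folding were higher and a few of sterol and retinoid metabolism lower in the same enterocyte-like cells, by small amounts. The ER stress list had a median log2 ratio of 0.16 (percentile 99.98), with 4 of 24 genes at least 1.5-fold higher and 20 between, led by sdf2l1 (1.80-fold higher), creld2 (1.63-fold) and pdia6 (1.58-fold), whose products help proteins fold. The list for retinoid and cholesterol metabolism had a median of -0.26 (percentile 0.01), with 3 of 17 genes at least 1.5-fold lower and 14 between, among them hmgcra, the rate-limiting enzyme gene of sterol synthesis, 1.56-fold lower, and fdps, which lies between, 1.35-fold lower. Of single genes, eevs, which serves the synthesis of the sunscreen gadusol (4.04 and 19.01 CPM, 4.70-fold higher), the lectin gene itln2 (2.73-fold), the metallothionein gene mt2 (2.24-fold) and the chitinase gene chia.3 (2.09-fold) were among the 12 highest. The bile acid response gene nr0b2a was the lowest, at 25.04 and 6.91 CPM (3.62-fold lower), and the dehydrogenase-like gene dhrs13l1 was 2.02-fold lower.

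Cluster 8 held more transcripts of inflammatory signals in the transected library. It is led by the chemokine gene ccl19a.1, the junction genes cldn2 and cldn7b and the keratin gene krt94, had 154 uninjured and 179 transected cells, and has no name because too few markers of any class led it. Its 11 measured cytokine and chemokine genes had a median log2 ratio of 1.22 (above all 10000 random lists), with 7 at least 1.5-fold higher and 1 at least 1.5-fold lower. The neutrophil attractants cxcl8a (346 and 1658 CPM, 4.80-fold higher, 4.53 to 5.09) and cxcl18b (201 and 993 CPM, 4.94-fold), ccl20a.3 (112 and 562 CPM, 5.03-fold), which belongs to a family that draws lymphocytes, and il34 (113 and 429 CPM, 3.80-fold), a growth factor of macrophages, led the list. The highest gene of the cluster was il17c, which epithelia make in response to microbes: 5 UMIs in 1 uninjured cell and 132 UMIs in 22 transected cells, 39.6-fold higher (16.5 to 124). Of its transected UMIs 5 cells held 65.9%. The cholesterol transport gene star was 6.11-fold higher. The lowest genes of cluster 8 are leading genes of cluster 11. Of these cnfn had 2071 and 1 UMIs, a ratio of 0.000724, and tcnba stood at 3795 and 10.1 CPM, with 5 uninjured cells holding 74.2% and 69.2% of their UMIs. A UMI of tcnba was found in 94.2% of uninjured and 13.4% of transected cells, and the gene stood at 2545 and 1603 CPM in the ambient RNA. The uninjured side of cluster 8 thus holds transcripts of another cluster that the transected side mostly lacks. The enterocyte lists of lipid absorption and of peptide and sugar absorption stood at -1.97 and -0.82, but most members lie under the ambient level, and the 4 peptide and sugar genes at or above it had a median of 0.32, so neither is described as lower.

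Cluster 8 also held more transcripts for DNA synthesis. The 21 measured S phase genes had a median log2 ratio of 0.76 (above all 10000 random lists), with 17 at least 1.5-fold higher and 0 lower, led by the nucleotide enzyme genes dut (24.5 and 88.2 CPM, 3.59-fold) and tyms (9.72 and 31.6 CPM, 3.25-fold). The Notch target genes her9 and her15.1, which hold back differentiation, were named after their values were seen and were 1.52-fold and 1.86-fold lower there, while the Notch list had a median of 0.13 (percentile 89.97), with 4 genes at least 1.5-fold higher, 4 lower and 5 between. Heat shock genes had a median of 0.30 (percentile 99.7).

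Lysosome-rich enterocyte-like cells (cluster 15), which take up and digest luminal protein, held fewer transcripts of that machinery in the transected library. The 21 measured endocytosis and lysosome genes had a median log2 ratio of -1.12 (below all 10000 random lists), with 16 at least 1.5-fold lower and 0 higher. The uptake receptor genes lrp2b (199 and 30.0 CPM, 6.64-fold lower), cubn (3.88-fold lower) and amn (4.11-fold lower) and the lysosomal protease gene lgmn (534 and 98.7 CPM, 5.41-fold lower) led it. Many genes of this list, these among them, are also markers that named the class. Lower values thus also mean that the transected cells match the name less well. With cells weighted equally the median was -2.15. That value gives more weight to shallow cells, and 53 of the 112 transected cells, with a median of 1083 UMIs, leave the class at Leiden resolution 2. Gut hormone genes (3.54) and cytokine genes (1.1) were higher in the same class. All 910 transected insl5a UMIs lie in 2 cells, the hormone median was -0.23 with cells weighted equally, and the cytokine median was -0.10 at Leiden resolution 2. The low sums leave few UMIs: 27 UMIs of lrp2b remain in the transected library, 92.6% of them in 5 cells, at median depths of the class of 4976 uninjured and 1925.5 transected UMIs.

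The same lysosome-rich class held more transcripts of S phase genes, in few cells. The 13 measured S phase genes had a median log2 ratio of 1.72 (above all 10000 random lists), with 12 at least 1.5-fold higher, led by dut (6.56-fold) and the replication clamp gene pcna (37.3 and 175 CPM, 4.69-fold). With the 5% of cells with most UMIs of each gene left out the median was 0.54, and with cells weighted equally it was 0.58. The value of 0.54 lies inside the middle 95% of random lists from the untrimmed sums, and none were drawn from trimmed sums. In the sum, 5 transected cells held 82.9% of the pcna UMIs and 87.6% of the dut UMIs. Among the 12 highest genes were ggt1a (50.8 and 473 CPM, 9.30-fold), which acts on glutathione, itln2 (7.19-fold), the NF-kappaB inhibitor gene nfkbiaa (4.95-fold) and the p53 target cdkn1a (3.17-fold). Scaling by the median of ratios in place of the total moves all genes of this class by 0.18 on the log2 scale.

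**Figure D2:**
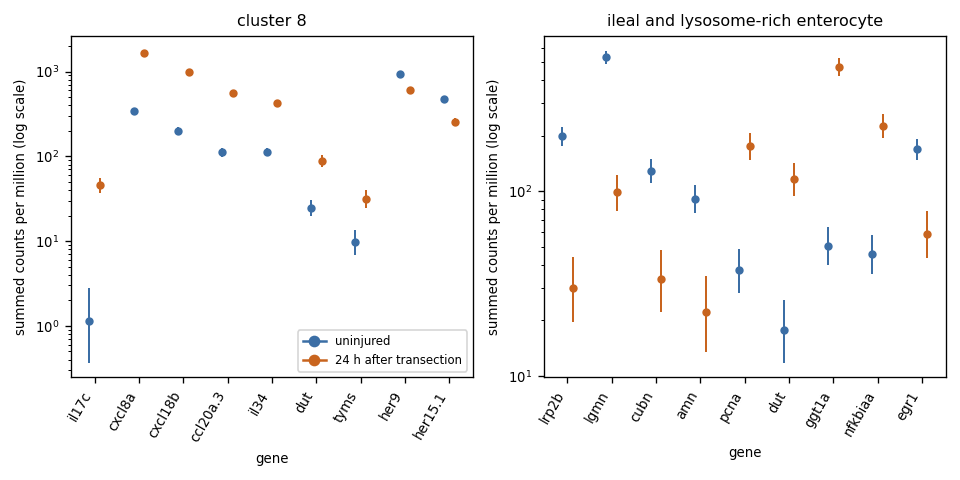
CPM from summed counts of chemokine, S phase and Notch target genes in cluster 8, and of uptake, S phase and other named genes in lysosome-rich enterocyte-like cells, with exact 95% intervals that cover counting error only. The her genes of cluster 8 were chosen after their values were seen.

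BEST4/OTOP2-like cells (clusters 18 and 21; 131 uninjured and 262 transected cells) held more transcripts of Hippo pathway genes, which set organ size, with their 2 clusters summed. The 6 measured YAP list genes had a median log2 ratio of 0.92 (percentile 99.6), with 5 at least 1.5-fold higher and 1 at least 1.5-fold lower: the co-activator gene yap1 stood at 64.9 and 128 CPM (1.97-fold) and its DNA-binding partners tead1a at 55.1 and 114 CPM (2.06-fold) and tead3b at 31.8 and 67.1 CPM (2.11-fold). The sorting receptor gene sorcs2 (6.26-fold) and the basement membrane gene fras1 (5.17-fold) were the 2 highest genes. But cluster 21 held 75.9% of the uninjured and 40.3% of the transected UMIs of the class and cluster 18 the rest. Within cluster 18 and cluster 21, a split made after the values were seen, the YAP list medians were 0.17 (percentile 82.1) and -0.09 (percentile 50.3). The list's difference in the sum goes with the mix of clusters, and neither yap1 nor tead3b was clearly higher in both. Within cluster 18 and cluster 21 the ratio of yap1 was 1.42 (1.02 to 1.99) and 1.13 (0.693 to 1.79), and that of tead3b 0.866 (0.591 to 1.29) and 3.62 (1.49 to 9.39). The Notch targets her9 (313 and 126 CPM, 2.48-fold lower) and her2 (2.46-fold lower) and the hormone-responsive gene klf9 (2.62-fold lower) were among the lowest. Within cluster 18 and cluster 21 the ratio of klf9 was 0.361 (0.239 to 0.542) and 0.484 (0.352 to 0.654), that of sorcs2 3.46 (1.97 to 6.55) and 3.11 (1.07 to 9.61), that of fras1 3.34 (2.00 to 5.92) and 1.45 (0.514 to 3.86), and that of her9 0.883 (0.592 to 1.34) and 0.483 (0.387 to 0.597). Endocytosis and lysosome genes had a median of -0.32 (percentile 0.78), and of -0.11 within each cluster.

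Enteroendocrine-like cells (cluster 20; 104 uninjured and 93 transected cells) differed in Notch targets, hormones and cytokines, each resting on a handful of cells. The 10 measured Notch genes had a median log2 ratio of -4.13 (below all 10000 random lists), with 9 at least 1.5-fold lower. The Notch target her15.1 stood at 513 and 7.88 CPM, but 5 uninjured cells held 94.5% of its UMIs, and 13 uninjured and 0 transected cells held at least 2, at median depths of 12412.5 and 7108 UMIs. Gut hormone genes had a median of 0.61 (above all 10000 random lists), with insl5a, an insulin-like hormone of the hindgut, at 812 and 4226 CPM and vipb and galn, 2 neuropeptide genes, 8.34-fold and 4.41-fold higher; 5 transected cells held 97.1% of the insl5a UMIs, and with the cells weighted equally the list median was -0.01. The motilin-like gene mlnl was 11.2-fold lower, with 5 uninjured cells holding 94.7% of its UMIs. Cytokine genes had a median of 2.02 (above all 10000 random lists), with tnfb at 22.2 and 206 CPM, in 4 and 6 cells. The angiotensinogen gene agt, which codes for a precursor of a blood pressure hormone, was 4.35-fold higher in 22 and 23 cells.

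The cytokine gene il22, which acts on epithelia to favour barrier defence, had UMIs in the enteroendocrine-like class of both libraries: 15 UMIs in 5 of 104 uninjured cells (4.81%, 1.58 to 10.9) and 17 UMIs in 3 of 93 transected cells (3.23%, 0.670 to 9.14), or 12.8 and 26.8 CPM, a ratio of 2.09 (0.983 to 4.50). In the ambient RNA il22 stood at 0.928 and 0.266 CPM. With ambient RNA put at 3.01% and 1.03% of the UMIs of the class, it would bring 0.033 and 0.0017 UMIs of il22. Outside the class 7 of 6045 uninjured cells (0.116%) and 2 of 5942 transected cells (0.034%) held a UMI. Absorptive enterocyte-like cells, which are not known to make il22, held a UMI in 1 of 1570 uninjured and 1 of 1939 transected cells, at median depths of 37137.5 and 29234 UMIs against 12412.5 and 7108 in the enteroendocrine-like class. With cells thinned to 1000 UMIs, leaving out 12 uninjured and 19 transected enteroendocrine-like cells that hold fewer, il22 was in 1 of 92 (1.09%) and 1 of 74 (1.35%). Over all cells il22 had 24 and 19 UMIs in 12 and 5 cells. The density gradient for live cells, the filter on UMIs and the lower depth of the transected library all bear on such shares.

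The IL-26 gene il26 and the IL-10 gene il10 were close to the limit of detection. For il26 there were 8 UMIs in 5 uninjured and 3 UMIs in 2 transected cells, a ratio of 0.559 (0.0955 to 2.33), with 4 of the 8 in cluster 7 and 2 of the 3 in cluster 8. All 8 il10 UMIs came from 4 of 99 uninjured leukocytes, and with 6 transected leukocytes a count of 0 says little. The receptor gene il10ra, which senses IL-10, had 145 UMIs in the uninjured and 8 in the transected library, 98 and 4 of them in leukocytes. The receptor gene crfb4 stood at 21.4 and 14.4 CPM in absorptive enterocyte-like cells, a ratio of 0.670 (0.617 to 0.727), under its level of 32.7 and 25.3 CPM in the ambient RNA of the libraries. Of the 24 names of the IL-10 family list 16 were matched in the files, and 3 to 7 were measured per class, so receptors such as il22ra1 and crfb14 are not covered. The measured part lay within the middle 95% of random lists in each of the 13 compared classes. In absorptive enterocyte-like cells its median log2 ratio was -0.10 (percentile 49.5).

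Cluster 10, which is led by agr2 and her15.1 and has 152 uninjured and 154 transected cells, held more transcripts of some secretory genes in the transected library. Mucus and goblet genes had a median log2 ratio of 0.46 (percentile 99.9), with 3 of 7 genes at least 1.5-fold higher, among them galnt7, which starts sugar chains on mucins, at 4.33-fold. ER stress genes had a median of 0.32 (above all 10000 random lists), with 6 of 22 at least 1.5-fold higher, and pdia6 was 1.60-fold higher. The enterocyte lists of lipid absorption and of peptide and sugar absorption stood at -1.81 and -1.09 there, not described as lower because their members lie mostly under the ambient level. STAT3-response genes had a median of -0.40 (percentile 1.06), the cofilin-like gene cfl1l was 2.68-fold higher and the fatty acid transport gene slc27a6 was 2.82-fold lower.

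Cluster 7, led by tcnba, neu3.3 and anxa4 (136 and 211 cells), went the other way for protein folding. Its ER stress genes had a median log2 ratio of -0.83, with sdf2l1 3.65-fold lower, and its retinoid and cholesterol genes -1.02, with hmgcs1 6.52-fold lower and sqlea, both of sterol synthesis, at a ratio of 0.0904 (0.0323 to 0.205). The antioxidant gene prdx1 stood at 1549 and 435 CPM, 3.56-fold lower, while mt2 was 2.52-fold higher. Its cytokine and chemokine genes had a median of 0.51 (above all 10000 random lists), with cxcl18b 1.63-fold higher. The enterocyte list of lipid absorption stood at -1.88 and the matrix list at -2.05, but members mostly lie under the ambient level, and the 4 matrix genes at or above it had a median of -0.15, so neither is described as lower. Another scaling moves all its genes by -0.15 on the log2 scale.

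The remaining compared classes gave values that rest on few cells. In cluster 23 the protease inhibitor gene timp2b was 13.7-fold higher and the acute-phase gene saa 25.2-fold higher, but 5 transected cells held 90.5% and 99.8% of their UMIs. In mesenchyme-like cells the growth factor binding gene igfbp1a was 5.36-fold higher, with 5 transected cells holding 97.8% of its UMIs, and the hypoxia and glycolysis list had a median log2 ratio of -0.63, with the glycolysis regulator pfkfb3 2.73-fold lower. Within clusters 13, 14 and 16 the list stood at -0.29, -0.13 and -1.31. The enterocyte list of peptide and sugar absorption stood at 1.54 in these mesenchyme-like cells, with members mostly under the ambient level. The forebrain gene foxg1a had 188 UMIs in uninjured and 1 in transected mesenchyme-like cells, a ratio of 0.0415 (0.00104 to 0.234), but 183 of the 188 lie in cluster 14, which holds 267 uninjured and 14 transected cells. In cluster 11 the actin bundle genes espn and myo3b were 5.57-fold and 5.79-fold higher and the sterol gene idi1 2.80-fold higher, where another scaling moves all genes by 0.41 on the log2 scale, as it does by 0.47 in cluster 23. In cluster 12 the limb and lung field gene tbx4 had 162 and 2 UMIs, a ratio of 0.0594 (0.00713 to 0.218). There the matrix gene bcan had 213 and 0, 14.8-fold lower with the 0 set to the floor of 3 counts. The gene osr2, of intermediate mesoderm, was 12.7-fold higher in 17 and 22 cells.

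**Figure D3:**
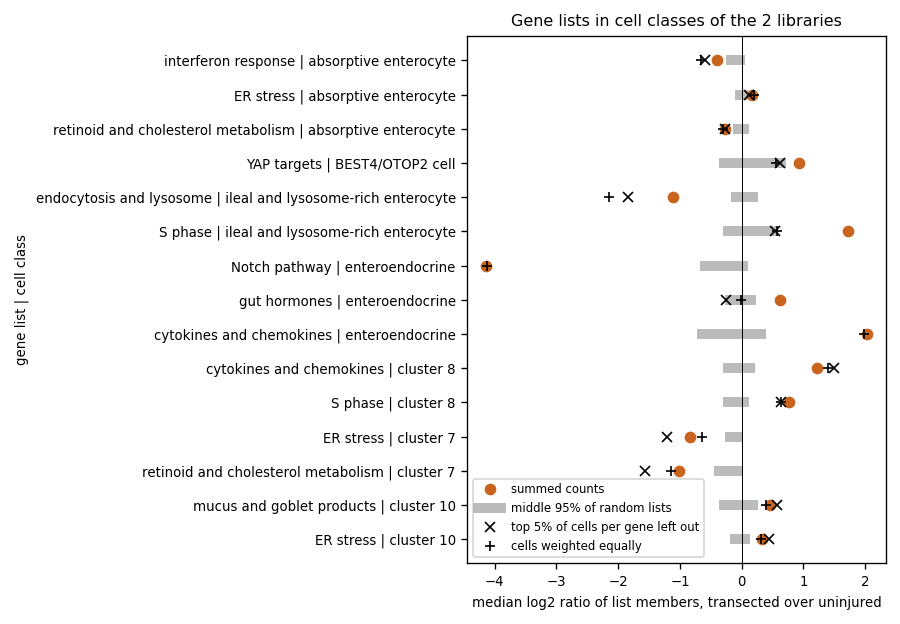
Median log2 ratio of 15 gene lists in named classes and numbered clusters, with the middle 95% of matched random lists from the summed counts. Also shown are the medians when cells are weighted equally or when the 5% of cells with most UMIs of each gene are left out. The Notch and cytokine lists of enteroendocrine-like cells have no value with those cells left out, and their gut hormone list reverses, and the YAP list of BEST4/OTOP2-like cells is at 0.17 and -0.09 within cluster 18 and cluster 21.

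The share of dividing cells was alike in the 2 libraries by the count of cells after thinning, but summed cell-cycle transcripts were lower in the transected library. Over all cells G2/M genes stood at 79.4 (77.9 to 81.0) and 64.4 (62.8 to 66.2) CPM. S phase genes stood at 240 (237 to 242) and 220 (217 to 223) CPM. With every cell thinned to 1000 UMIs, 53 of 5249 uninjured (1.01%, 0.757 to 1.32) and 39 of 3876 transected cells (1.01%, 0.716 to 1.37) held at least 2 UMIs of mitosis genes such as ube2c and mki67, with 900 and 2159 shallower cells left out; without thinning the shares were 9.84% and 5.1%. Absorptive enterocyte-like cells, which rarely divide, had 1 of 1554 and 4 of 1918 such cells after thinning, at median depths of 37137.5 and 29234 UMIs. Cells of the cycling cluster numbered 62 and 74, at median depths of 30516 and 1136.5 UMIs, so their sums rest on few deep cells: there the Notch target her9 was 5.13-fold lower, with 5 transected cells holding 94.5% of its UMIs, and the lymphocyte receptor gene ccr9a had 530 and 0 UMIs, at least 82.6-fold lower. The lectin gene itln2 was 15.9-fold higher in 9 and 14 cells, and another scaling moves all genes of this cluster by 0.26 on the log2 scale.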

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

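The tests with low-UMI clusters left out or counted as enterocytes, with members at or above ambient, with the deepest 5% of cells left out and with the 5% of cells with most UMIs of each gene left out were chosen after the data were seen. Of 169 values for shares of cells 125 stayed inside the counting interval and 2 reversed, of 938 values for lists 804 stayed within the spread of random lists and 17 reversed, and of 724 values for genes 627 stayed inside and 2 reversed; all 14 values for cycling shares stayed inside. These totals pool settings that move little, such as ambient subtraction (81 of 81 gene values inside), with others: with the 5% of cells with most UMIs of each gene left out 29 of 76 gene values and 24 of 52 list values stayed inside, 2 and 5 reversed, and with cells weighted equally 55 of 81 and 41 of 59 stayed inside. Equal median depth thins sums by 1 factor for all genes, so it shows counting error only. Over all 372 genes picked by the naming rule or named, 39 of 3311 values reversed. The log2 ratio of il22 in enteroendocrine-like cells and the leukocyte share stayed inside their intervals in each alternative run. The cause was not tested for any value that follows, beyond what each setting leaves out.

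The share ratio of absorptive enterocyte-like cells (1.26) was 1.67 and 1.77 at minimums of 1000 and 2000 UMIs. At Leiden resolution 0.5 and 2 it was 0.839 (reversed) and 1.57. The reversed value leaves out an unnamed cluster of 20 and 652 cells, the numbers of enterocyte cluster 4 at resolution 1. With low-UMI clusters left out or counted as enterocytes the ratio was 1.81 and 1.84. The latter counts clusters 0, 3 and 6, whose enterocyte markers can be partly ambient RNA. That of mesenchyme-like cells (0.151) was 0.192, 0.205 and 0.217 at 1000 and 2000 UMIs and without low-UMI clusters, where BEST4/OTOP2-like cells stood at 2.93 against 2.04. Stratified epithelium went to 1.15 at resolution 2 from 0.0425, because the cluster led by stm and sparc (17 and 103 cells) also took that name. The krt5-led cluster held 74 and 0 cells there.

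With the 5% of cells with most UMIs of each gene left out, medians were -0.59 for interferon genes in absorptive enterocyte-like cells, 1.49 for cytokines in cluster 8, and 0.54 for S phase and -1.84 for lysosome genes in the lysosome-rich class. Reversed were gut hormones in enteroendocrine-like cells (-0.26), STAT3 genes in cluster 11 (0.016), and in cluster 23 acute-phase (-0.19), protease (-0.21) and p53 genes (-0.28) and saa (-0.51), and insl5a in the lysosome-rich class (-0.14 against 6.88, from 2 transected cells). The Notch and cytokine lists of enteroendocrine-like cells kept under 3 members and have no value there, and neither has il22, whose UMIs lie in few cells. With the deepest 5% of cells left out, S phase in the lysosome-rich class was 2.57, and acute-phase (-0.51) and p53 genes (-0.26) of cluster 23 reversed.

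With cells weighted equally, interferon genes stood at -0.66, and lysosome and S phase genes of the lysosome-rich class at -2.15 and 0.58; reversed were heat shock in low-UMI barcodes (-0.12), G2/M in cluster 10 (0.052), and gut hormones in the lysosome-rich (-0.23) and enteroendocrine-like class (-0.013). At equal median depth gut hormones of the latter stood at 0.88, and S phase of the cycling cluster reversed (0.13). With doublets kept, enteroendocrine-like cytokines, Notch genes and hormones stood at 1.15, -3.73 and 0.33.

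At Leiden resolution 0.5 interferon genes stood at -0.63, lysosome genes at -0.55, and enteroendocrine-like cytokines, Notch genes and hormones at 1.06, -2.92 and 0.33; YAP genes of mesenchyme reversed (0.16). At resolution 2 enteroendocrine-like Notch genes stood at -3.05 and cytokines of the lysosome-rich class reversed (-0.10). Neither resolution was run for lists of numbered clusters or for single genes, so their dependence on the clustering was not tested.

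With a pseudocount of 10 CPM interferon genes stood at -0.22, S phase at 0.50 in cluster 8 and 1.12 in the lysosome-rich class, lysosome genes at -0.87, and enteroendocrine-like Notch genes and cytokines at -2.37 and 1.27; with 1 CPM that Notch list stood at -3.70. With members of at least 1 count, cytokines in cluster 8 stood at 0.60, lysosome genes at -0.79, and enteroendocrine-like cytokines, Notch genes and hormones at 0.88, -2.02 and 0.88; reversed were cytokines in cluster 11 (1.01) and acute-phase genes in cluster 12 (2.85). With at least 100 counts, cytokines in cluster 8 stood at 1.93, enteroendocrine-like hormones at 0.88, and S phase of the cycling cluster reversed (0.047). Interferon members at or above ambient gave -1.18.

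Leaving out replicates was not possible with 1 library per group. The minimum of 1000 UMIs was not run for cycling shares, since thinning to 1000 already imposes it. The lower depth of the transected library (a median of 2796 against 8638 UMIs) limits shares of cells with a UMI there.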

Other observations

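Immediate early genes, such as egr1, which cells switch on within minutes of a stimulus or of dissociation, were lower in the transected library in 9 of the 13 compared classes and higher in 0 by the rule for lists. Their median log2 ratios ran from -0.45 in cluster 10 to 0.30 in cluster 11. Within single clusters they were -0.15 and -0.24 in BEST4/OTOP2-like and -0.13, -0.13 and -0.22 in mesenchyme-like cells, nearer 0 than in the whole classes. In enteroendocrine-like cells egr1 stood at 151 and 42.6 CPM, and in lysosome-rich enterocyte-like cells at 169 and 58.8 CPM. In BEST4/OTOP2-like cells btg2, a gene that slows division, was 1.80-fold lower, at ratios of 0.595 (0.484 to 0.732) within cluster 18 and 0.694 (0.602 to 0.798) within cluster 21.

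The tests of explanations that follow were all chosen after the results they address were seen. Notch target genes such as her15.1 and her2 were lower in transected enteroendocrine-like cells. Ambient RNA is argued against as the whole cause, since the median log2 ratio was -4.18 with ambient counts subtracted. Depth stays open: with every cell thinned to 1000 UMIs only 1 of the 10 genes kept enough counts to be measured. A candidate explanation is that a few uninjured cells, such as young cells leaving a Notch-active state or doublets with another epithelial cell, carry the transcripts: over the 10 measured genes, 5 uninjured cells held a median of 93.3% of the UMIs. Whether transection removed such cells or 1 library missed them by chance stays open with 1 library per group.

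Mesenchyme-like cells, leukocytes and endothelium-like cells held smaller shares in the transected library. More low-UMI barcodes in the denominator are argued against as the whole cause, since without them the highest ratio among these classes and the smooth muscle genes of cluster 17 was 0.217. Less tissue from outside the gut in the dissected sample may account for part: cartilage, heart, skin and liver clusters together held 486 uninjured and 9 transected cells, a ratio of 0.0189, and with exocrine pancreas 558 and 26 cells, a ratio of 0.0475. Part of the mesenchyme-like class may also come from outside the gut, since cluster 13 is led by and2, a gene of the larval fin fold. Loss of gut-wall cells after transection cannot be told apart from less tissue or poorer release of cells for cluster 17 (a ratio of 0.109), because dissection and group go together.

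In lysosome-rich enterocyte-like cells lysosome genes such as lgmn were lower and S phase genes such as pcna higher. For the lysosome genes, depth is argued against as the whole cause. With every cell thinned to 1000 UMIs the 12 genes that could be measured, of 21, had a median log2 ratio of -2.13. This lies below the middle 95% of random lists. Thinning also weights cells equally, so shallow cells that may be of another kind count fully there. Other cells sharing the cluster cannot be told apart from a change in the cells themselves. The median was -0.95 at Leiden resolution 2, but the 53 transected cells left out there hold only 12.4% of the UMIs of the class, too few to move the sum, and the 910 insl5a UMIs in 2 cells go with mixing. For the S phase genes, a candidate explanation is that a few dividing cells carry the transcripts. Without the 5% of cells with most UMIs of each gene the median was 0.54, against 1.72 with them. This lies just inside the middle 95% of random lists (up to 0.55). Those lists were drawn from the untrimmed sums only, so that comparison cannot decide. Many lysosome list genes are also markers that named the class, so their lower values also mean a poorer match of the transected cells to the name. A loss of uptake machinery by these cells after transection was not tested and stays open.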
